A study of Mus musculus with 12 samples.

How the data were processed

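Ventricular tissue of male and female C57BL/6 mice kept in normoxia or hypoxia was profiled by RNA sequencing in 12 libraries, 3 for each combination of sex and oxygen. Per the labels' protocols, RNA came from frozen hearts and the libraries were made with a directional mRNA kit that keeps the strand of origin. Per the submitters' processing notes, reads were checked with FastQC and quantified with Salmon, with GRCm39 named as the genome build; versions, the annotation release and the setting used for strand were not given in the sources used here. Per the file headers, the deposited table gives for each gene and library an estimated count of reads, an abundance in TPM (transcripts scaled by length and library) and an average effective transcript length. The estimated counts deposited by the authors were not scaled from abundance. The deposited TPM values summed to between 889905 and 926060 per library. They were used only to describe the table, and 0 columns of per-sample values belonged to no sample.

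All tests started from the deposited estimated counts, rounded to whole numbers. The table held 39210 genes under Ensembl identifiers. A symbol was found for 99.3% of them and 269 had none. The annotation used for symbols belongs to another build than the one named by the submitters, so it served for names alone and no coordinates are given. Library totals ranged from 14915800 to 19397900 estimated counts. Genes with too few reads were removed with edgeR's filterByExpr on the 4 groups, which left 13960 genes. Scaling used TMM factors. edgeR 4.0.16 in R 4.3.3 fitted a group-means model to all 12 libraries together, with 8 residual degrees of freedom, and glmQLFTest gave a two-sided test of each contrast. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test unless another tool is named, and a gene passed at an adjusted p under 0.05. Standard errors were derived from the log2 fold change and the F statistic. Levels are CPM, counts scaled to library sizes corrected here by TMM, given as mean ± SD with n = 3 per group.

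The contrasts were hypoxia against normoxia in males, in females and averaged over both, the female effect minus the male effect (the interaction), and females against males at each oxygen level. The contrasts, their statistical tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. The tests of explanations for Myl7, female normoxia library 3 and the mitosis genes were chosen after the results were seen. The rule named, for each hypoxia contrast, the 8 genes with the largest rise and the 8 with the largest fall among those that passed, with a mean log2 CPM of at least 1 and no overlap between hypoxia and normoxia libraries of the same sex, which chance gives for 10% of genes with 3 libraries against 3. For the averaged contrast the absence of overlap had to hold in both sexes and in the same direction, which chance gives less often. Predicted, Y-linked and immune receptor genes were skipped. It also named up to 4 members of each list that was called or had at least 3 members past the threshold, up to 2 members of other lists, the 10 genes with the smallest interaction p, the sex-linked list with up to 5 further genes per sex contrast, and 7 genes of prior interest (Nppa, Nppb, Myh7, Myh6, Mki67, Vegfa and Hba-a1). Genes named outside it are marked as such, apart from a further set of atrial genes, fixed after the atrial markers were seen but before its own values were. Some genes that the rule names are not reported here.

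The 42 gene lists covered oxygen and energy metabolism, stress responses, contraction, the cell cycle, matrix, vessels, inflammation, the clock and markers of the cell types that heart tissue can hold. Of these, 40 had at least 5 tested members. Markers of platelets and megakaryocytes, with 4 tested members, and of lung epithelium, with 2, were not tested. For each list the members past the threshold were counted over all genes tested and again with p-values adjusted over the list alone. limma 3.58.1 camera compared each list with the other genes on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists of a contrast. It was repeated with the correlation estimated per list, and fry tested whether a list's genes moved on balance one way. None of the calls from the preset correlation held with an estimated correlation. By fry, which does not compare a list with the other genes, 19 lists passed in the averaged contrast (12 up and 7 down). It called 12 lists in males (9 up and 3 down), 7 in females (5 up and 2 down) and 0 for the interaction.

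Alternatives were DESeq2 1.42.0, limma voom, RLE or upper quartile factors, no filter or a stricter one, removal of mitochondrially encoded and haemoglobin genes, the replicate number as a block, only the compared libraries, a log2 fold threshold of 1, and each library left out in turn. Added after the data were seen were an offset for the deposited transcript lengths and fits without libraries that stood apart: male hypoxia libraries 2 and 3, alone or together with female normoxia library 3. Each fit repeated the filter, so the genes tested could differ between fits. Other assignments of the libraries to groups were fitted as well, at most 100 per result. A fold against a group with 0 reads is a lower bound, computed with 3 reads over the group in place of 0. Such bounds cover counting error only.

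The steps were tested on simulated counts, drawn independently for each gene around its mean over all 12 libraries. No library was made to stand apart, so the recovery rates may not hold for the real data. Among genes above a minimum mean count, 100 were changed 2-fold and 100 were changed 4-fold. For hypoxia in males edgeR recovered 57% and 85% of these over 13739 genes, with 5 false calls, and for hypoxia in females 61% and 83% over 13754 genes, with 3. For the averaged effect it recovered 74% and 95% over 13767 genes, with 9 false calls, and for the interaction 28% and 75% over 13752 genes, with 1. The sex contrast gave 61% and 87% over 13761 genes in normoxia, with 7 false calls, and 52% and 87% over 13749 genes in hypoxia, with 5. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.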

Results

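Gene expression was measured in ventricular tissue of C57BL/6 mice by strand-specific mRNA sequencing. The 12 libraries fell into 4 groups of 3: males in normoxia, males in hypoxia, females in normoxia and females in hypoxia. In the hypoxia groups chamber oxygen was stepped down by 1% per day over 14 days to a final 7%, held for 2 weeks, whereas normoxic mice breathed 20.9% oxygen for 4 weeks. The labels do not separate the left from the right ventricle. The mean total per library was 18067400 ± 1187240 estimated counts (SD, n = 3) in normoxic males, 16927600 ± 1742880 in hypoxic males, 17200900 ± 947550 in normoxic females and 17161300 ± 268446 in hypoxic females. The labels do not state that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

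Oxygen was the main axis of variation. The first principal component held 25.8% of the variance and ran from -40.3 to -20.6 in the normoxia libraries and from 2.68 to 47.2 in the hypoxia libraries. Haemoglobin transcripts made up 0.169 ± 0.0352% of counts in normoxic males and 0.169 ± 0.0166% in normoxic females, against 1.21 ± 0.163% and 0.904 ± 0.183% in hypoxic males and females. The share of mitochondrially encoded transcripts was 28.3 ± 0.845% and 25.4 ± 0.969% in normoxic males and females and 20.3 ± 3.93% and 22.2 ± 0.782% in hypoxic ones. Some libraries stood apart from the rest of their group. Male hypoxia libraries 2 and 3 had mean log2 CPM values of atrial cardiomyocyte markers of 6.52 and 6.07, against 2.90 to 4.09 in the other 10, and of adipocyte markers of 5.11 and 4.84, against at most 3.64. Female normoxia library 3 lay at -69.7 on the second component (12.7% of the variance). It had a mean log2 CPM of immediate early genes of 5.27, against 2.55 to 3.6 elsewhere. Female hypoxia library 1 lay at 2.68 on the first component, against 37.5 and 41.1 for female hypoxia libraries 2 and 3.

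**Figure D1:**
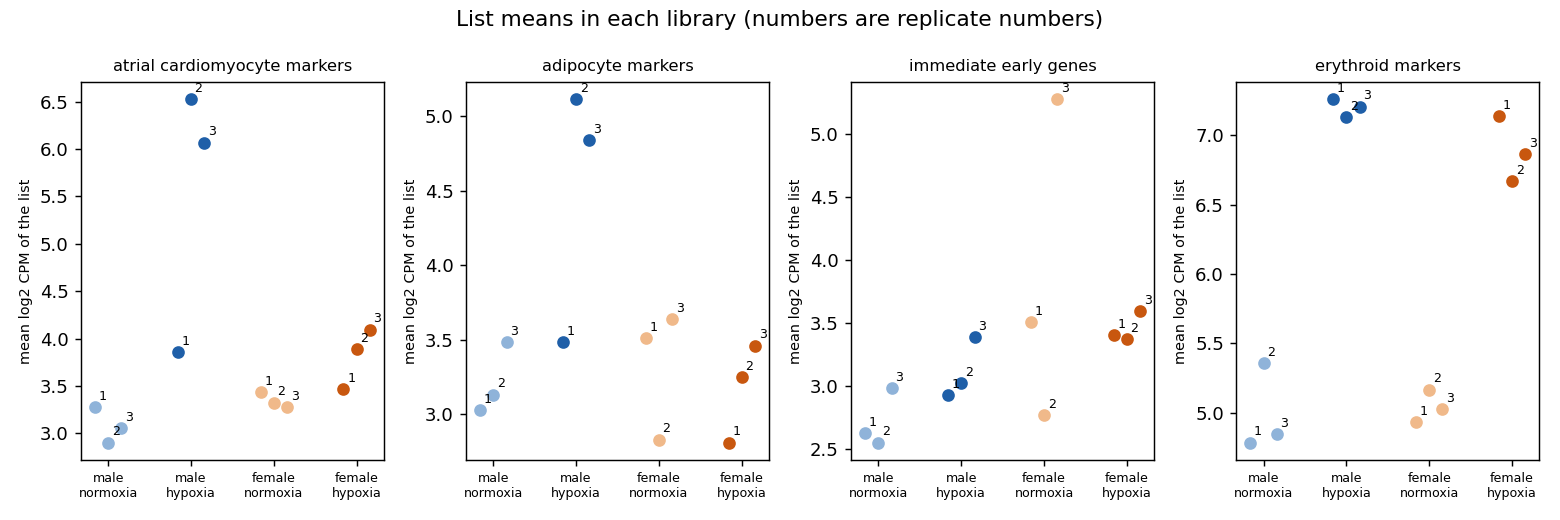
Mean log2 CPM of the atrial, adipocyte, immediate early and erythroid lists in each of the 12 libraries, by group, with each point a library. Atrial scores were 6.52 and 6.07 in male hypoxia libraries 2 and 3 and at most 4.09 in the others.

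The contrast of hypoxia averaged over sexes asked what weeks of low oxygen changed in the ventricles, as the mean of the male and female effects. Genes of red blood cells, mitosis, extracellular matrix and endothelium rose, and genes of fatty acid oxidation and the mitochondrial genome fell. The alpha-globin gene Hba-a1 (ENSMUSG00000069919) went from 687 ± 122 to 4070 ± 366 CPM in males and from 680 ± 102 to 3174 ± 992 CPM in females (SD, n = 3), a mean rise of 5.26-fold (log2 2.39 ± 0.16, SE, adjusted p = 1.26e-05). The proliferation marker Mki67 (ENSMUSG00000031004) rose 3.74-fold (log2 1.90 ± 0.23, adjusted p = 0.000475), and the matrix protein gene Postn (ENSMUSG00000027750) rose 6.26-fold (log2 2.65 ± 0.38, adjusted p = 0.000993). Cpt2 (ENSMUSG00000028607), which encodes an enzyme of mitochondrial fatty acid import, fell by 1.01 on the log2 scale (SE 0.12, adjusted p = 0.000466). In total 2100 genes were higher and 1796 lower in hypoxia, of which 463 and 159 changed at least 2-fold. Of the 40 lists tested camera called 19, 11 up and 8 down. Without male hypoxia libraries 2 and 3 the total of 3896 genes dropped to 1295, and without female normoxia library 3 as well it was 2329. The lone male hypoxia library of these fits was assumed to vary like the other groups.

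**Figure D2:**
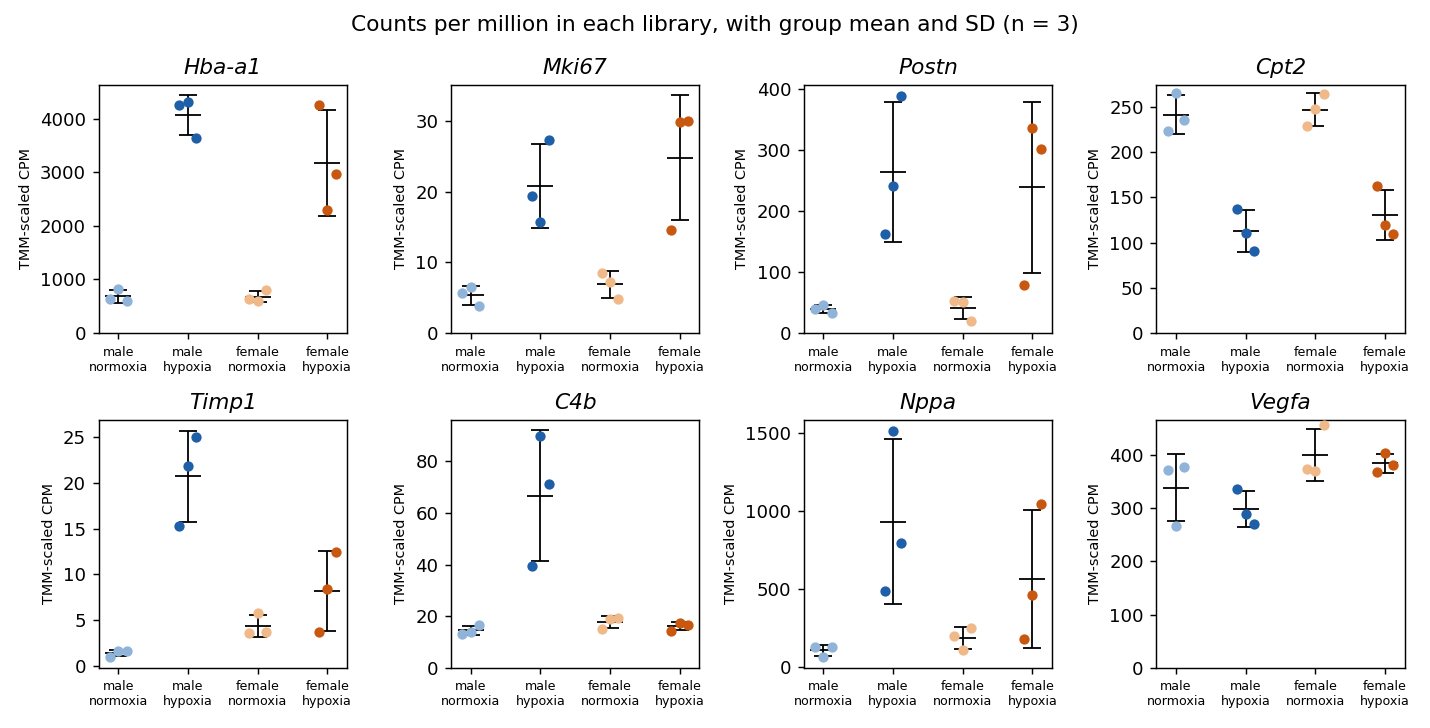
TMM-scaled CPM of Hba-a1, Mki67, Postn, Cpt2, Timp1, C4b, Nppa and Vegfa in every library (points), with the mean and SD of each group of 3 (bars). Vegfa was at 339 ± 62.2 and 298 ± 34.0 CPM in normoxic and hypoxic males, whereas Hba-a1 was at 687 ± 122 and 4070 ± 366 CPM.

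Erythroid genes showed the largest median rise among the called lists. Of 11 tested markers 9 rose over all genes and adjusted over the list alone. Over all members the median log2 fold change was 2.48 (camera adjusted p = 2.92e-09, adjusted p = 0.308 with an estimated correlation). Alas2 (ENSMUSG00000025270), which starts haem synthesis in red cell precursors, rose from 12.2 ± 4.48 to 117 ± 9.23 CPM in males and from 14.0 ± 1.42 to 97.0 ± 23.8 CPM in females (averaged log2 3.03 ± 0.17, adjusted p = 7.71e-06). The beta-globin gene Hbb-bs rose by a log2 of 2.48 ± 0.13 (adjusted p = 7.71e-06). Reads of Hba-a1 and Hba-a2 (2.31 ± 0.14, adjusted p = 9.28e-06), and of Hbb-bs and Hbb-bt (2.50 ± 0.16, adjusted p = 1.26e-05), may be shared between near-identical copies, so the split within each pair is uncertain.

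Genes of cell division rose together. Of 36 tested mitosis genes 31 rose and 1 fell, and 33 rose and 1 fell adjusted over the list alone. The list's median log2 fold change was 1.75 (camera adjusted p = 3.2e-14, adjusted p = 0.386 with an estimated correlation). Besides Mki67, the members with the smallest adjusted p were Prc1, a spindle midzone protein (log2 2.05 ± 0.25, adjusted p = 0.000474), the mitotic cyclin gene Ccnb1 (2.49 ± 0.31, adjusted p = 0.000492) and the spindle motor gene Kif11 (1.74 ± 0.23, adjusted p = 0.000682). Of 27 DNA replication genes 8 rose and none fell, with the same count adjusted over the list alone, and the median was 0.51 (camera adjusted p = 0.000876, adjusted p = 0.582 with an estimated correlation). E2f1, a transcription factor that drives entry into S phase, rose by a log2 of 1.17 ± 0.16 (adjusted p = 0.000867), and Clspn, a replication checkpoint gene, by 1.89 ± 0.37 (adjusted p = 0.00441). Among cell cycle inhibitors and D cyclins 2 of 14 genes rose and 1 fell, with 1 rising and none falling adjusted over the list alone (camera adjusted p = 0.3). Trp53 was the member with the smallest p (0.63 ± 0.14, adjusted p = 0.00816). With male hypoxia libraries 2 and 3 left out, 23 of 37 mitosis genes and 2 of 28 replication genes rose.

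Matrix genes rose almost throughout the list. Of 37 tested genes 31 rose and none fell, and 33 rose adjusted over the list alone. Over all members the median log2 fold change was 1.36 (camera adjusted p = 3.85e-14, adjusted p = 0.386 with an estimated correlation). Examples were Lox, which crosslinks collagen (log2 2.28 ± 0.25, adjusted p = 0.000358), the fibronectin gene Fn1 (1.67 ± 0.20, adjusted p = 0.000473), the collagen gene Col12a1 (2.78 ± 0.34, adjusted p = 0.000498) and the secreted glycoprotein gene Spp1 (3.07 ± 0.34, adjusted p = 0.000342). Of 14 fibroblast markers 6 rose and none fell, and 7 rose and 1 fell adjusted over the list alone. The median was 0.30 (camera adjusted p = 0.018, adjusted p = 0.582 with an estimated correlation). They included Meox1 (1.14 ± 0.21, adjusted p = 0.0032) and Col1a1 (1.32 ± 0.21, adjusted p = 0.00175), a member of both lists. In females alone 1 of 14 fibroblast markers rose, also adjusted over the list alone (median 0.26, camera adjusted p = 0.138). In the fit without male hypoxia libraries 2 and 3, 18 matrix genes and 2 fibroblast markers rose.

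Endothelial markers rose in 11 of 14 members over all genes and adjusted over the list alone. The list's median log2 fold change was 0.63 (camera adjusted p = 1.25e-06, adjusted p = 0.386 with an estimated correlation). The von Willebrand factor gene Vwf rose from 46.1 ± 4.91 to 129 ± 18.6 CPM in males and from 50.7 ± 9.29 to 123 ± 35.1 CPM in females (averaged log2 1.38 ± 0.15, adjusted p = 0.000313). Mmrn2 (0.81 ± 0.09, adjusted p = 0.000317) and Eng (0.89 ± 0.11, adjusted p = 0.000585) also rose. Of 25 angiogenesis genes 9 rose and 2 fell, and 11 rose and 2 fell adjusted over the list alone. The median was 0.26 (camera adjusted p = 0.007, adjusted p = 0.552 with an estimated correlation). They included the chemokine receptor gene Cxcr4 (1.33 ± 0.12, adjusted p = 0.000132) and the endothelial transcription factor gene Sox18 (1.01 ± 0.12, adjusted p = 0.000465). Vegfa (ENSMUSG00000023951), the main vascular growth factor gene, did not pass (log2 -0.12 ± 0.10, adjusted p = 0.405). Leaving out male hypoxia libraries 2 and 3, 7 endothelial markers and 3 angiogenesis genes rose.

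Genes of fatty acid oxidation fell. Of 26 tested members 22 fell and none rose, and 23 fell adjusted over the list alone. Over all members the median log2 fold change was -0.70 (camera adjusted p = 9.92e-12, adjusted p = 0.416 with an estimated correlation). Cpt2 went from 242 ± 21.7 to 113 ± 23.1 CPM in males and from 247 ± 18.1 to 131 ± 28.1 CPM in females. Other members that fell included the fatty acid carrier gene Fabp3 (-0.84 ± 0.11, adjusted p = 0.000597) and the trifunctional protein subunit gene Hadhb (-0.95 ± 0.13, adjusted p = 0.00073). Of 13 PPAR-alpha targets 8 fell, and 9 adjusted over the list alone. The median was -0.83 (camera adjusted p = 0.000109, adjusted p = 0.549 with an estimated correlation). Members past the threshold included the peroxisomal enzyme gene Ehhadh (-0.93 ± 0.17, adjusted p = 0.0029). The receptor gene Ppara fell as well (-1.09 ± 0.27, adjusted p = 0.0135). It is a regulator of mitochondrial biogenesis, and of these 5 of 11 fell and 1 rose (7 and 1 adjusted over the list alone, median -0.38, camera adjusted p = 0.007, adjusted p = 0.582 with an estimated correlation). Without male hypoxia libraries 2 and 3, 9 genes of fatty acid oxidation, 2 PPAR-alpha targets and none of the biogenesis regulators fell by edgeR's test. In female normoxia library 3 the mean log2 CPM of the PPAR-alpha targets was 7.04, against 5.79 to 5.98 in the other normoxia libraries.

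Transcripts of the respiratory chain fell as well. Of 13 mitochondrially encoded mRNAs 9 fell, and all 13 adjusted over the list alone. The list's median log2 fold change was -0.52 (camera adjusted p = 2.41e-06, adjusted p = 0.386 with an estimated correlation). Among them were mt-Atp6 (-0.75 ± 0.10, adjusted p = 0.000802) and mt-Co1 (-0.54 ± 0.11, adjusted p = 0.00531). The table also lists abundant nuclear pseudogenes of near-identical sequence, so their exact levels are uncertain. Of 42 nuclear-encoded genes of oxidative phosphorylation 14 fell, and 20 adjusted over the list alone. The median was -0.24 (camera adjusted p = 3.92e-08, adjusted p = 0.582 with an estimated correlation). They included Cox7a1 (-0.67 ± 0.11, adjusted p = 0.00171). Of 18 tricarboxylic acid cycle genes 6 fell, and 12 adjusted over the list alone. The median was -0.33 (camera adjusted p = 2.91e-05, adjusted p = 0.582 with an estimated correlation). Members past the threshold included Sucla2 (-0.52 ± 0.10, adjusted p = 0.00359). Without male hypoxia libraries 2 and 3, 9 mitochondrially encoded mRNAs, 1 nuclear-encoded gene and 1 cycle gene fell.

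Hypertrophy and fetal cardiac genes rose in 8 of 17 members over all genes and adjusted over the list alone. Over all members the median log2 fold change was 0.86 (camera adjusted p = 0.000178, adjusted p = 0.567 with an estimated correlation). Nppa (ENSMUSG00000041616), the atrial natriuretic peptide gene that stressed ventricles re-express, rose by 2.36 ± 0.43 (adjusted p = 0.00299), and Mybpc2, a myosin binding protein gene, by 1.95 ± 0.20 (adjusted p = 0.000269). Nppb (0.90 ± 0.55, adjusted p = 0.238), the slow myosin gene Myh7 (adjusted p = 0.212) and its adult counterpart Myh6 (adjusted p = 0.188) did not pass. Without female normoxia library 3 Myh7 did, at 2.11 (adjusted p = 0.00514), and Nppb, at 1.62 (adjusted p = 0.0208), as Myh6 did without female hypoxia library 1, at -0.58 (adjusted p = 0.00542). Nppa, Myl4 and Myl7 are also atrial genes, which were high in male hypoxia libraries 2 and 3, and without these 5 of 18 members rose. Calcium handling and ion channel genes fell in 7 of 21 members and rose in 1 over all genes and adjusted over the list alone. The median was -0.23 (camera adjusted p = 0.00976, adjusted p = 0.601 with an estimated correlation). Among them were the calcium-binding protein gene Hrc (-0.74 ± 0.12, adjusted p = 0.00203) and the calcium pump regulator gene Pln (-0.55 ± 0.11, adjusted p = 0.00442). In females alone 0 of 21 passed over all genes, and 1 rose and 2 fell adjusted over the list alone (median -0.21, camera adjusted p = 0.0725). The sodium channel subunit gene Scn4b (ENSMUSG00000046480), not on that list, fell from 43.1 ± 6.05 to 8.91 ± 3.23 CPM in males and from 37.6 ± 5.97 to 6.79 ± 2.17 CPM in females (-2.38 ± 0.19, adjusted p = 4.76e-05).

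Inflammatory genes rose in 8 of 20 members and fell in 1, and 10 rose and 1 fell adjusted over the list alone. The list's median log2 fold change was 0.53 (camera adjusted p = 0.007, adjusted p = 0.386 with an estimated correlation). The chemokine genes Ccl8 (2.36 ± 0.43, adjusted p = 0.00296) and Ccl2 (1.27 ± 0.27, adjusted p = 0.00656) and the adhesion gene Icam1 (0.81 ± 0.13, adjusted p = 0.0016) were among them. Macrophage and monocyte markers rose in 6 of 15 members over all genes and adjusted over the list alone. The median was 0.33 (camera adjusted p = 0.00531, adjusted p = 0.582 with an estimated correlation). They included Cd68 (0.99 ± 0.20, adjusted p = 0.00514). Lymphocyte markers fell in 2 of 6 over all genes and adjusted over the list alone. The median was -0.78 (camera adjusted p = 0.023, adjusted p = 0.386 with an estimated correlation). Members past the threshold included the B cell gene Cd22 (-1.12 ± 0.28, adjusted p = 0.0126). The lymphocyte call was lost without male normoxia library 3 (adjusted p = 0.0549) or male hypoxia library 2 (adjusted p = 0.0548) or on voom values (adjusted p = 0.0632). Genes of the integrated stress response rose in 9 of 21 members and fell in 1, and 10 rose and 1 fell adjusted over the list alone. The median was 0.47 (camera adjusted p = 0.00531, adjusted p = 0.308 with an estimated correlation). Among them were the serine synthesis gene Psat1 (0.86 ± 0.17, adjusted p = 0.00409) and the asparagine synthetase gene Asns (0.85 ± 0.19, adjusted p = 0.00691). Without male hypoxia libraries 2 and 3, 4 inflammatory genes, 4 macrophage markers and 2 stress response genes rose, and none of the lymphocyte markers fell by edgeR's test. In females alone, none of the 20 inflammatory genes (median 0.14, camera adjusted p = 0.273), 21 stress response genes (median 0.26, camera adjusted p = 0.0596) or 6 lymphocyte markers (median -0.07, camera adjusted p = 0.684) passed, over all genes or adjusted over the list alone. Of 15 macrophage and monocyte markers 1 rose in females, also adjusted over the list alone (median 0.19, camera adjusted p = 0.102).

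**Figure D3:**
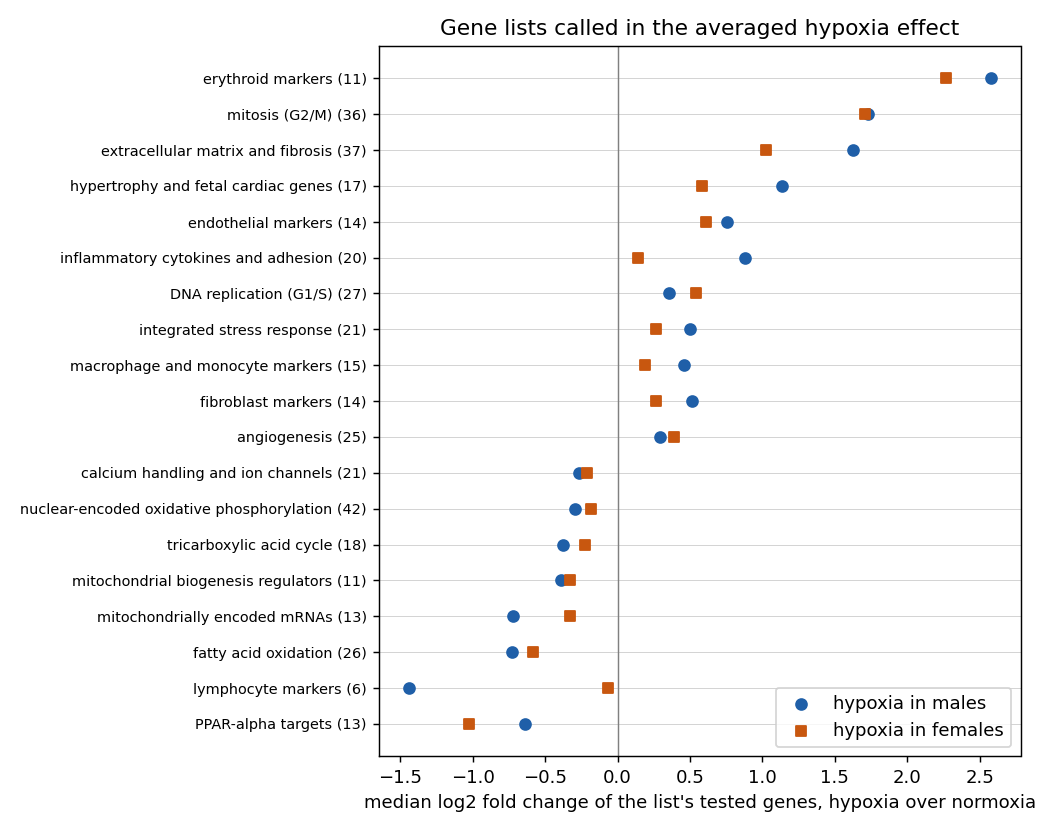
Median log2 fold change in hypoxia (horizontal axis) of each of the 19 lists called in the averaged contrast (vertical axis). Each list has a circle for males and a square for females. Erythroid markers had medians of 2.58 in males and 2.27 in females, and fatty acid oxidation genes of -0.73 and -0.59.

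In males alone mitosis, matrix and erythroid genes rose, fatty acid oxidation genes fell, and several single genes rose by large amounts. Alas2 rose (log2 3.26 ± 0.24, adjusted p = 0.000121), as did the matrix protease inhibitor gene Timp1 (ENSMUSG00000001131), from 1.44 ± 0.321 to 20.7 ± 4.94 CPM (SD, n = 3; log2 3.84 ± 0.42, adjusted p = 0.00103). The acute phase gene Serpina3n rose from 8.84 ± 3.11 to 147 ± 38.9 CPM (4.06 ± 0.52, adjusted p = 0.00174). Hmox1, which degrades haem, rose from 8.50 ± 2.32 to 106 ± 22.9 CPM (3.63 ± 0.48, adjusted p = 0.00207), and the nicotinamide riboside kinase gene Nmrk2 from 3.36 ± 1.34 to 46.0 ± 27.2 CPM (3.79 ± 0.54, adjusted p = 0.00245). The MHC class II gene H2-Aa fell from 52.4 ± 16.5 to 9.16 ± 0.478 CPM (-2.52 ± 0.27, adjusted p = 0.00101), and H2-Ab1 (-2.48 ± 0.28, adjusted p = 0.00107) and Cd74 (-2.29 ± 0.26, adjusted p = 0.00106) fell as well. Scn4b (-2.29 ± 0.26, adjusted p = 0.00107) and the sodium-proton exchanger gene Slc9a2 (-2.47 ± 0.29, adjusted p = 0.00126) also fell. The atrial genes Myl4 (5.0 ± 0.85, adjusted p = 0.00515), Myl7 (7.79 ± 1.49, adjusted p = 0.00802) and Nppa (3.10 ± 0.62, adjusted p = 0.00995) passed, with Myl7 at 1214 and 1060 reads in male hypoxia libraries 2 and 3 and at most 15 in any other library. With limma voom Myl4 did not (adjusted p = 0.114).

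In all, 1183 genes were higher and 991 lower in hypoxic males, 498 and 182 of them at least 2-fold, and camera called 19 lists, 11 up and 8 down. In mitosis 25 of 36 genes rose and 1 fell (31 and 1 adjusted over the list alone, median 1.73, camera adjusted p = 1.61e-12, adjusted p = 0.425 with an estimated correlation). In the matrix list 28 of 37 rose (32 adjusted over the list alone, median 1.62, camera adjusted p = 5.71e-14, adjusted p = 0.425 with an estimated correlation). Among erythroid markers 9 of 11 rose, also adjusted over the list alone (median 2.58, camera adjusted p = 5.41e-10, adjusted p = 0.212 with an estimated correlation). In fatty acid oxidation 16 of 26 genes fell (21 adjusted over the list alone, median -0.73, camera adjusted p = 4.07e-10, adjusted p = 0.516 with an estimated correlation). Inflammatory genes rose in 9 of 20 members and fell in 1 (10 and 1 adjusted over the list alone, median 0.88, camera adjusted p = 0.000587, adjusted p = 0.337 with an estimated correlation). Hypertrophy genes rose in 6 of 17 (8 adjusted over the list alone, median 1.14, camera adjusted p = 2.12e-05, adjusted p = 0.519 with an estimated correlation). Without male hypoxia libraries 2 and 3 none of 18 hypertrophy genes passed, with a median of 0.59. Glucocorticoid targets rose in 3 of 15, also adjusted over the list alone (median 0.56, camera adjusted p = 0.0315, adjusted p = 0.581 with an estimated correlation), a call lost without male normoxia library 3 (adjusted p = 0.0705) or male hypoxia library 1 (adjusted p = 0.0665) or 2 (adjusted p = 0.125). Of 6 atrial markers 4 rose, also adjusted over the list alone. The median was 3.43 (camera adjusted p = 0.119). The total of 2174 dropped to 953, 1301 and 1070 without male normoxia library 1, 2 or 3, to 994 and 877 without male hypoxia library 2 or 3, and to 66 without both of the latter. In that last fit 6 erythroid markers and 3 matrix genes rose, and no mitosis gene passed by edgeR's test, with a list median of 1.60.

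In hypoxic females erythroid, mitosis and matrix genes were higher and fatty acid oxidation genes lower. Alas2 (log2 2.79 ± 0.24, adjusted p = 0.000381) and Hbb-bt (2.41 ± 0.23, adjusted p = 0.000692) rose, and Mki67 went from 6.88 ± 1.91 to 24.8 ± 8.83 CPM (SD, n = 3; 1.85 ± 0.33, adjusted p = 0.0127). Ankrd37 (ENSMUSG00000050914), known as a target of hypoxia-inducible factor in other settings, fell from 5.15 ± 0.278 to 0.627 ± 0.117 CPM (-3.03 ± 0.29, adjusted p = 0.000751), and in males by 2.18 on the log2 scale (SE 0.28, adjusted p = 0.00168). Scn4b fell by 2.47 (SE 0.27, adjusted p = 0.00158). Postn went from 41.1 ± 18.7 to 238 ± 139 CPM (2.54 ± 0.53, adjusted p = 0.0252), Col12a1 (2.37 ± 0.48, adjusted p = 0.0218) and Nmrk2 (2.29 ± 0.49, adjusted p = 0.0267) passed as well. Each of these last 3 calls was lost without female hypoxia library 2 or 3 (adjusted p from 0.0759 to 0.122), female normoxia library 2 (adjusted p from 0.0717 to 0.0828) or female normoxia library 1 (adjusted p from 0.0506 to 0.0561). Col12a1 was also lost with limma voom (adjusted p = 0.0737).

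For hypoxia in females 554 genes were higher and 282 lower, 206 and 58 of them at least 2-fold, and camera called 13 lists, 7 up and 6 down. Mitosis genes rose in 19 of 36 members and fell in 1 (29 and 1 adjusted over the list alone, median 1.71, camera adjusted p = 4.91e-15, adjusted p = 0.539 with an estimated correlation). Matrix genes rose in 10 of 37 (26 adjusted over the list alone, median 1.03, camera adjusted p = 2.5e-11, adjusted p = 0.548 with an estimated correlation). Female hypoxia library 1 had a mean log2 CPM of matrix genes of 4.62, against 5.58 and 5.71 in the other hypoxic females and 3.98 to 4.47 in normoxic ones. For mitosis genes it was 1.27, against 2.31 and 2.35 and 0.0666 to 0.845. Erythroid markers rose in 8 of 11 (9 adjusted over the list alone, median 2.27, camera adjusted p = 2.5e-11, adjusted p = 0.369 with an estimated correlation). Fatty acid oxidation genes fell in 8 of 26 (24 adjusted over the list alone, median -0.59, camera adjusted p = 1.39e-11, adjusted p = 0.539 with an estimated correlation). PPAR-alpha targets fell in 5 of 13 (11 adjusted over the list alone, median -1.03, camera adjusted p = 8.31e-06, adjusted p = 0.539 with an estimated correlation), and without female normoxia library 3 in 2 of 14, with a median of -0.47. Hypertrophy genes rose in 2 of 17 (3 adjusted over the list alone, median 0.58, camera adjusted p = 0.0203, adjusted p = 0.761 with an estimated correlation), a call lost without female normoxia library 1 (adjusted p = 0.0769) or 2 (adjusted p = 0.152) or female hypoxia library 1 (adjusted p = 0.0582) or 3 (adjusted p = 0.0673). Nppa stood at 185 ± 71.9 CPM in normoxic and 564 ± 441 CPM in hypoxic females (1.61 ± 0.59, adjusted p = 0.121). The total of 836 was 233 and 147 without female normoxia library 1 or 2, 75 and 55 without female hypoxia library 2 or 3, and 2081 without female hypoxia library 1. Only 40 genes passed when the 6 female libraries were fitted alone, and DESeq2 called 1693. Without female normoxia library 3 the count was 997, with 12 of 37 mitosis genes (median 1.52) and 3 of 26 fatty acid oxidation genes (median -0.47) past the threshold.

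The effects in both sexes pointed mostly the same way. Both sexes raised Alas2, Mki67 and Postn and lowered Scn4b, Ankrd37 and Cpt2. Across the 13960 genes, which are not independent replicates, the male and female log2 fold changes correlated with a Pearson r of 0.415 and a Spearman rho of 0.583. The calls shared 356 higher and 167 lower genes, where independent lists would share 46.9 and 20, and 1 gene was called in opposite directions. Of the male calls 95.5% had the same sign in females, and of the female calls 97.7% had the same sign in males. The slope of the female on the male log2 fold change over the male calls was 0.524, a value that selection of genes by their male effect lowers. Pearson's r was 0.250 with DESeq2, 0.130 with no filter on low counts and 0.265 without female hypoxia library 3. With each library left out it was 0.265 to 0.403, below the main value in every case. Those fits repeated the filter on fewer libraries, so their genes differ and the drop cannot be assigned to the library removed.

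The interaction contrast asked whether the response to hypoxia differed between the sexes, and it called 1 gene. Hdgfl2 (ENSMUSG00000002833), chosen after its values were seen because the naming rule required a higher mean level, had 91 to 114 reads in the normoxic female libraries and 0 in all 3 hypoxic ones, at least 99.4-fold lower in hypoxia. Whether these zeros arose in the samples or in the quantification was not decided. It rose in males (log2 1.35 ± 0.24, adjusted p = 0.00909, interaction adjusted p = 0.000128). The genes with the next smallest p did not pass with edgeR. The complement gene C4b (ENSMUSG00000073418) was at 14.5 ± 1.86 and 66.8 ± 25.4 CPM in normoxic and hypoxic males (SD, n = 3) and at 17.8 ± 2.28 and 16.1 ± 1.56 CPM in females (interaction log2 -2.35 ± 0.35, adjusted p = 0.0973). The chemokine gene Ccl9 had an interaction of -1.74 ± 0.25 (adjusted p = 0.0973), and Slc26a10 one of 1.44 ± 0.21 (adjusted p = 0.0973), with 17.8 ± 2.24 and 55.7 ± 2.47 CPM in normoxic and hypoxic females. Timp1, at 4.39 ± 1.22 and 8.20 ± 4.38 CPM in females, had an interaction of -2.93 ± 0.55 (adjusted p = 0.292). At an unadjusted p under 0.05 there were 948 genes, and DESeq2 called 65 (14 up and 51 down), among them C4b, Ccl9, Slc26a10 and Timp1, whereas voom called 2. The edgeR count was 6 with no filter, 7 without male hypoxia libraries 2 and 3, and 5 without male hypoxia library 1, which brought in C4b (adjusted p = 0.000732). It was 2 without male hypoxia library 2 or 3 or female hypoxia library 3, the last with Ccl9 past the threshold (adjusted p = 0.0424).

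By camera 14 lists had an interaction, negative in 11 and positive in 3. None held with an estimated correlation (smallest adjusted p = 0.307 with an estimated correlation), fry called 0, and no member of any of them passed over all genes in edgeR's test. Matrix genes had a median interaction of -0.44 (camera adjusted p = 0.000612, adjusted p = 0.715 with an estimated correlation), with 1 of 37 lower adjusted over the list alone, a call lost without female hypoxia library 1 (adjusted p = 0.227). Inflammatory genes had a median of -0.88 (camera adjusted p = 0.000612, adjusted p = 0.54 with an estimated correlation), with 3 of 20 lower adjusted over the list alone. Lymphocyte markers had a median interaction of 1.44, from medians of -1.44 in males and -0.07 in females (camera adjusted p = 0.000612, adjusted p = 0.307 with an estimated correlation), with none of 6 past the threshold adjusted over the list alone. Atrial markers, high in male hypoxia libraries 2 and 3, had a median of -2.06 (camera adjusted p = 0.049, adjusted p = 0.58 with an estimated correlation), with 3 of 6 lower adjusted over the list alone. Immediate early genes, high in female normoxia library 3, had a median of -1.10 (camera adjusted p = 0.00415, adjusted p = 0.715 with an estimated correlation). The atrial call was lost without male hypoxia library 2 (adjusted p = 0.121) or 3 (adjusted p = 0.0665) or female normoxia library 1 (adjusted p = 0.0556), and that of immediate early genes without female normoxia library 3 (adjusted p = 0.635). Those of inflammatory genes and lymphocyte markers passed with any 1 library left out.

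In normoxia most of the genes that differed between females and males were sex-linked. The X-inactivation transcript Xist (ENSMUSG00000086503) was at 275 ± 11.1 CPM in normoxic females and 0.359 ± 0.219 CPM in normoxic males (SD, n = 3; log2 9.54 ± 0.27, adjusted p = 3.62e-09). The Y-linked genes Ddx3y (-10.32 ± 0.33, adjusted p = 1.17e-08), Eif2s3y (-10.24 ± 0.28, adjusted p = 3.62e-09), Uty (-5.24 ± 0.40, adjusted p = 9.57e-05) and Kdm5d (-4.32 ± 0.22, adjusted p = 1.59e-06) were lower in females. These 5 genes match the labelled sex of every group. In normoxia 6 genes were higher and 4 lower in females, against 1018 at an unadjusted p under 0.05. The balance of directions varied with the fit: 60% of the 10 genes were higher in females, against 69% with DESeq2, 37.5% with voom, 33.3% with the replicate block or only the compared libraries, and 16.7% to 33.3% with each normoxia library left out. Of the 9 sex-linked genes 4 were higher and 4 lower (5 and 4 adjusted over the list alone, median 0.71, mean -1.94, camera adjusted p = 0.621, fry adjusted p = 0.000143). The X-linked genes Kdm5c (0.84 ± 0.11, adjusted p = 0.0138) and Eif2s3x (0.74 ± 0.10, adjusted p = 0.0271), which escape X inactivation, were higher in females. Kdm5c was lost without male normoxia library 1 (adjusted p = 0.0841), 2 (adjusted p = 0.132) or 3 (adjusted p = 0.0672), and Eif2s3x without any 1 of the 6 normoxia libraries (adjusted p from 0.0631 to 0.166). The total of 10 was 5 without male normoxia library 1 and 6 without any other normoxia library, and DESeq2 called 58. By camera 8 lists differed, 6 up and 2 down. Immediate early genes had the smallest adjusted p, with a median of 1.22 (camera adjusted p = 1.15e-06, adjusted p = 0.899 with an estimated correlation), 11 of 19 higher adjusted over the list alone and none over all genes, and were high in female normoxia library 3.

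In hypoxia 5 genes were higher and 16 lower in females, against 1345 at an unadjusted p under 0.05. Xist (10.11 ± 0.27, adjusted p = 3.14e-09) and the 4 Y-linked genes separated the sexes again. Of the 9 sex-linked genes 3 were higher and 4 lower (5 and 4 adjusted over the list alone, median 0.42, mean -2.27, camera adjusted p = 0.413, fry adjusted p = 5.48e-05). C4b was 2.05 lower on the log2 scale in hypoxic females (log2 -2.05 ± 0.25, adjusted p = 0.00605), the signalling gene Dixdc1 was lower (-1.32 ± 0.17, adjusted p = 0.00974), and so was Wfdc17 (-1.67 ± 0.23, adjusted p = 0.0181). Dixdc1 was lost without male hypoxia library 2 (adjusted p = 0.0544) or female hypoxia library 3 (adjusted p = 0.0645), and Wfdc17 without male hypoxia library 2 (adjusted p = 0.0816) or female hypoxia library 2 (adjusted p = 0.148). C4b did not pass when the 6 hypoxia libraries were fitted alone (adjusted p = 0.104). The total of 21 was 9 without male hypoxia library 2, 11 without female hypoxia library 2 or 3, and 40 without male or female hypoxia library 1. DESeq2 called 184. The balance of directions varied too: 23.8% of the 21 genes were higher in females, against 52.2% with DESeq2, 62.5% without female hypoxia library 1 and 60% without male hypoxia libraries 2 and 3. By camera 11 lists differed, 3 up and 8 down, led by endoplasmic reticulum chaperones (median -0.32, camera adjusted p = 1.84e-05, adjusted p = 0.803 with an estimated correlation). Next came neutrophil markers (median -1.56, camera adjusted p = 0.000451, adjusted p = 0.732 with an estimated correlation) and lymphocyte markers (median 1.07, camera adjusted p = 0.00156, adjusted p = 0.437 with an estimated correlation). None of their members passed over all genes in edgeR's test, and 4 of 6 neutrophil markers were lower adjusted over the list alone.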

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

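Of the tests below, the search for further atrial genes and the other assignments of libraries to groups were chosen before their results were seen; the tests on Myl7 in the other hypoxia libraries and on female normoxia library 3, and the reading of the atrial search by baseline, were chosen only after the result was seen.

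A test of the interaction between sex and hypoxia called 1 gene with edgeR and 14 gene lists with camera. None of the lists held with an estimated correlation (smallest adjusted p = 0.307 with an estimated correlation), and fry called 0. The gene was Hdgfl2, which encodes a chromatin-associated protein (interaction adjusted p = 0.000128). It had 31 to 154 reads in the 9 libraries outside the hypoxic female group and 0 in the 3 hypoxic female ones. Whether these zeros arose in the samples or in the quantification was not decided. Each single library also had 1 to 10 genes with 0 reads there and at least 20 in every other library. The interaction count of 1 was matched or exceeded in 14 of 100 assignments of the libraries, the real one included, the highest other count being 2. These assignments exchanged the sexes within each oxygen level, so differences between the sexes can enter their counts. The share is therefore not a chance rate in the absence of an interaction, and chance was not excluded for the count. At an unadjusted p under 0.05 there were 948 genes, and DESeq2 called 65 and voom 2.

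Inflammatory, neutrophil and matrix lists had a negative interaction (female minus male effect) by camera, with no member past the threshold over all genes. Inflammatory genes had a median interaction of -0.88 and neutrophil markers one of -1.73 (camera adjusted p = 0.000612 each, adjusted p = 0.54 and 0.58 with an estimated correlation), with 3 of 20 and 3 of 6 lower adjusted over the list alone. The neutrophil median was 0.95 in males and -0.79 in females. Matrix genes had a median of -0.44 (camera adjusted p = 0.000612, adjusted p = 0.715 with an estimated correlation), a call lost without female hypoxia library 1 (adjusted p = 0.227). Lymphocyte markers, at 1.44, and mitochondrially encoded mRNAs, at 0.39, had positive interactions (camera adjusted p = 0.000612 each, adjusted p = 0.307 and 0.58 with an estimated correlation), and so did nuclear-encoded genes of oxidative phosphorylation, at 0.10 (camera adjusted p = 0.0351, adjusted p = 0.826 with an estimated correlation). The last call was lost without male normoxia library 3 (adjusted p = 0.25), male hypoxia library 3 (adjusted p = 0.958), female normoxia library 1 (adjusted p = 0.0662) or 2 (adjusted p = 0.104), or female hypoxia library 1 (adjusted p = 0.62). For mitochondrially encoded mRNAs male hypoxia library 2 stood apart, with a mean log2 CPM of 12.11 against 12.78 and 12.77 in male hypoxia libraries 1 and 3.

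Stress and signalling lists had negative interactions as well. NRF2 and antioxidant genes had a median of -0.24 (camera adjusted p = 0.00097, adjusted p = 0.58 with an estimated correlation; 2 of 25 lower adjusted over the list alone), and glucocorticoid targets one of -0.50 (camera adjusted p = 0.00295, adjusted p = 0.58 with an estimated correlation; 1 of 15 lower adjusted over the list alone). Endoplasmic reticulum chaperones were at -0.20 (camera adjusted p = 0.0199, adjusted p = 0.715 with an estimated correlation) and muscle atrophy genes at -0.39 (camera adjusted p = 0.00944, adjusted p = 0.58 with an estimated correlation). Hypertrophy genes were at -0.75 (camera adjusted p = 0.00487, adjusted p = 0.715 with an estimated correlation), and immediate early genes at -1.10 (camera adjusted p = 0.00415, adjusted p = 0.715 with an estimated correlation). The chaperone call was lost without male normoxia library 2 (adjusted p = 0.19) or 3 (adjusted p = 0.222), male hypoxia library 3 (adjusted p = 0.169), female normoxia library 2 (adjusted p = 0.0531) or 3 (adjusted p = 0.0762), or female hypoxia library 2 (adjusted p = 0.116). That of atrophy genes was lost without male hypoxia library 2 (adjusted p = 0.0743), that of hypertrophy genes without male hypoxia library 3 (adjusted p = 0.147) or female normoxia library 3 (adjusted p = 0.0902), and that of immediate early genes without female normoxia library 3 (adjusted p = 0.635).

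Atrial and adipocyte markers also had negative interactions, and male hypoxia libraries 2 and 3 held the high values. The atrial list had a median interaction of -2.06 (camera adjusted p = 0.049, adjusted p = 0.58 with an estimated correlation) and the adipocyte list one of -0.93 (camera adjusted p = 0.0135, adjusted p = 0.58 with an estimated correlation), with 3 of 6 and 1 of 7 lower adjusted over the list alone. The atrial call was lost without male hypoxia library 2 (adjusted p = 0.121) or 3 (adjusted p = 0.0665) or female normoxia library 1 (adjusted p = 0.0556), and the adipocyte call without male hypoxia library 2 (adjusted p = 0.0569). The atrial light chain gene Myl7 had 1214 and 1060 reads in male hypoxia libraries 2 and 3 and at most 15 in any other. Sln, an atrial list member named outside the rule, had 339 and 225 reads in these libraries and at most 3 in any other.

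For male hypoxia libraries 2 and 3, atrial tissue in these 2 libraries is a candidate explanation. The test set beforehand asked whether most of a further set of atrial genes were higher in both libraries than in all others, and the answer went against it: 1 of 5 measured genes was, Mybphl, with 143 and 113 reads against at most 5 elsewhere. Sbk2 (31 to 156 reads), Stard10 (129 to 426) and Nr2f1 (38 to 96) were read in every library, a baseline that could hide a small atrial share. Only Mybphl had a low baseline and enough reads, where 3 such genes were needed, so the explanation stays open. A rise as large as in these 2 libraries was absent from the 4 other hypoxia libraries. Myl7 had 4 to 15 reads there, against 1214 and 1060. That argues against such a rise in every exposed heart, for Myl7. Whether hypoxia raised the atrial genes by a smaller amount in every exposed heart stays open. Myl7 exceeded every normoxia library of the same sex in 2 of the 4 other hypoxia libraries, at counts near the floor.

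Female normoxia library 3 stood apart from the other normoxia libraries by immediate early genes and PPAR-alpha targets, and also by the mean log2 CPM of cytosolic heat shock genes (7.04 against 5.94 to 6.26) and of hypertrophy genes (6.35 against 4.84 to 5.59). A hypoxia library under a normoxia label was excluded, since its mean log2 CPM of erythroid markers was 5.03, within 4.78 to 5.36 of the other normoxia libraries and below 6.67 to 7.26 of the hypoxia libraries. Shallower sequencing was excluded as well, as its total was 17818700 counts with a median of 17502300 over all libraries. The design names no group that separates it, and no biological explanation was tested.

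For the other contrasts the real assignment gave more genes than any other tried. With both sexes it called 3896 genes and the highest other called 1305. Of 100 assignments fitted, out of 200 possible, 1 was as large, the real one itself. That argues against an arbitrary grouping of these libraries. Chance between animals was not tested, because the labels do not state that the libraries came from separate animals. Hypoxia gave 2174 genes in males with 0 as the highest other and 836 in females with 13, and sex gave 10 in normoxia with 0 and 21 in hypoxia with 1. For these 4 contrasts 10 splits are too few for a share under 0.05.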

How the results depend on the processing

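The settings chosen only after the result was seen were the transcript length offset and the fits without male hypoxia libraries 2 and 3, alone or with female normoxia library 3. The counts that follow in this paragraph cover neither these settings nor the fold threshold. Of 194 gene calls named, 140 passed under every other alternative, 54 were lost in some (19 of them only when a library was left out) and 0 reversed. Over all gene and list results, 4726 values were on the same side of the threshold when a library was left out, 289 were weaker, 150 stronger and 1 turned direction; with the other alternatives 2519 were on the same side, 202 weaker and 34 stronger. The 1 that turned was the list mitochondrially encoded mRNAs, sex in hypoxia, without male hypoxia library 2 (camera adjusted p = 0.796, the highest with each library left out; the lowest was 0.00239).

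For hypoxia in males the 2174 genes became 1265 with the length offset, 66 without male hypoxia libraries 2 and 3, 176 without these and female normoxia library 3, 680 at a log2 fold of at least 1, and 877 to 2129 with each library left out. For hypoxia in females the 836 became 1693 with DESeq2, 362 with the length offset, 40 with only the compared libraries, 264 at that fold, and 55 to 2081 with each library left out. For hypoxia averaged over sexes the 3896 became 1295 and 2329 in those fits without 2 and 3 libraries, 622 at that fold, and 2685 to 4635 with each library left out.

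The interaction's 1 gene became 65 with DESeq2, 2 with voom, 6 with no filter, 7 and 6 in the same fits, and 1 to 5 with each library left out. Sex in normoxia, 10 genes, gave 58 with DESeq2, 6 with the replicate block, only the compared libraries or the fold threshold, and 5 to 6 with each library left out. Sex in hypoxia, 21 genes, gave 184 with DESeq2, 13 with the length offset, 12 without those 3 libraries or with only the compared libraries, and 9 to 40 with each library left out. Pearson's r between the sexes, 0.415, was 0.250 with DESeq2, 0.130 with no filter and 0.265 to 0.403 with each library left out. The 19 averaged list calls became 0 with an estimated correlation and 18 to 23 with each library left out. The fold threshold passes fewer genes by construction; for the other changes the cause was not tested.

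With the replicate block the counts were 2268 for hypoxia in males, 800 for hypoxia in females, 3931 for hypoxia averaged over sexes, 1 for the interaction, 6 for sex in normoxia and 14 for sex in hypoxia. Residuals of libraries with the same number correlated at -0.05 to 0.19, and the own number was the best match in 7 of 12 pairs. Between the oxygen levels of a sex the correlations were -0.0454 to 0.0286. Between the sexes they were 0.0313 to 0.0873 in normoxia and 0.047 to 0.186 in hypoxia. The labels name no block, so the numbers were not read as pairs. A factor shared by number across the sexes was not excluded.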

Other observations

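The tests on mitosis genes below were chosen only after the result was seen. Targets of hypoxia-inducible factor did not move as a group in the averaged contrast. Of 32 HIF-1 targets 6 rose and 4 fell, with the same counts adjusted over the list alone (median 0.08, camera adjusted p = 0.504), and of 21 glycolysis genes 5 rose and 6 fell (6 and 6 adjusted over the list alone, median 0.12, camera adjusted p = 0.504). Ldha, which makes lactate, rose by a log2 of 0.84 ± 0.08 (adjusted p = 0.000132), and Ldhb, which favours its use, fell by 0.67 (SE 0.11, adjusted p = 0.00201). Ankrd37 fell by 2.60 (SE 0.20, adjusted p = 4.66e-05), and Vegfa was at -0.12 ± 0.10 (adjusted p = 0.405).

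Heat shock and clock lists were not called by camera, and members of both moved in either direction. Over all 13960 genes tested, 3896 passed in the averaged contrast. The mitochondrial chaperone genes Hspe1 (-0.79 ± 0.09, adjusted p = 0.000358) and Hspd1 (-0.79 ± 0.09, adjusted p = 0.000401) fell, among 18 heat shock genes of which 3 rose and 4 fell (4 and 5 adjusted over the list alone, median -0.05, mean 0.05, camera adjusted p = 0.666). Female normoxia library 3 had the highest mean of these genes of all libraries, and without it 7 rose and 5 fell by edgeR's test, with a median of 0.12. Hspe1 and Hspd1 were still lower in hypoxia and past the threshold without it. The clock repressor gene Nr1d1 fell by 1.33 (SE 0.27, adjusted p = 0.00467) and Cry1 rose by 0.88 ± 0.20 (adjusted p = 0.00906), with 2 of 17 clock genes higher and 3 lower (2 and 4 adjusted over the list alone, median -0.25, camera adjusted p = 0.666). The hour of harvest was not given in the sources used here. Averaged over the sexes the MHC class II gene H2-Aa fell by 1.81 (SE 0.19, adjusted p = 0.000269).

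Several lists of other cell types and structures had members that changed, although the list was not called. Pericyte and smooth muscle markers rose in 6 of 13 members and fell in 1, also adjusted over the list alone (median 0.40, camera adjusted p = 0.128, or 0.0201 without male hypoxia library 1), with Rgs5 at 0.61 ± 0.13 (adjusted p = 0.00626). Epicardial markers rose in 2 of 6, also adjusted over the list alone (median 0.52, camera adjusted p = 0.44), namely Krt19 (3.85 ± 0.48, adjusted p = 0.00054) and Wt1 (1.07 ± 0.17, adjusted p = 0.00155). Lymphatic markers rose in 2 of 7 and fell in 1, also adjusted over the list alone (median 0.24, camera adjusted p = 0.528), with Prox1 at -0.48 ± 0.11 (adjusted p = 0.00958). Atrial markers rose in 4 of 6 (4 and 2 lower adjusted over the list alone, median 2.40, camera adjusted p = 0.3, or 0.00342 without male hypoxia library 1). Adipocyte markers rose in 1 of 7, also adjusted over the list alone (median 0.51, camera adjusted p = 0.666), and Schwann cell and neuron markers in 2 of 8, also adjusted over the list alone (median -0.21, mean 0.48, camera adjusted p = 0.989). Ventricular sarcomere genes fell in 4 of 17, also adjusted over the list alone (median -0.14, camera adjusted p = 0.178, or 0.0215 without female hypoxia library 1), among them Myl2 (-0.37 ± 0.09, adjusted p = 0.0103). By edgeR 0 of 5 fast skeletal muscle genes (median -0.13, camera adjusted p = 0.989) and 0 of 6 neutrophil markers (median 0.25, camera adjusted p = 0.84) passed, over all genes or adjusted over the list alone.

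Stress pathways were mixed. NRF2 and antioxidant genes rose in 5 of 25 members and fell in 4 (5 and 5 adjusted over the list alone, median -0.13, mean 0.07, camera adjusted p = 0.989), with Gpx1 at 0.78 ± 0.09 (adjusted p = 0.000435). Interferon targets fell in 3 of 29 and in 0 adjusted over the list alone (median -0.23, camera adjusted p = 0.234, or 0.0492, 0.0258 and 0.011 without male normoxia library 1, male hypoxia library 1 or female normoxia library 3). Glucocorticoid targets rose in 3 of 15 (2 adjusted over the list alone, median 0.26, camera adjusted p = 0.314), and immediate early genes rose in 2 of 19 and fell in 1, also adjusted over the list alone (median -0.25, mean 0.08, camera adjusted p = 0.989). The mean log2 CPM of immediate early genes was 5.27 in female normoxia library 3, against 3.51 and 2.77 in female normoxia libraries 1 and 2. In hypoxic females it was 3.37 to 3.60, so the female change depends on that library. Endoplasmic reticulum chaperones rose in 1 of 19 (0 adjusted over the list alone, median 0.15, camera adjusted p = 0.3, or 0.00953 without male normoxia library 1). Muscle atrophy and proteolysis genes rose in 1 of 15 and fell in 2, also adjusted over the list alone (median -0.11, camera adjusted p = 0.504), with Fbxo32 at -0.83 ± 0.19 (adjusted p = 0.00904). None of the 9 sex-linked genes passed by edgeR, over all genes or adjusted over the list alone (median -0.19, camera adjusted p = 0.559).

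Mitosis genes rose with a median log2 fold change of 1.75 and a lower quartile of 1.59. A lower share of cardiomyocytes alone would raise the other cell types by a similar amount. The highest median among 5 other cell type lists was 0.63 (endothelial), which argues against it for these cell types. Lymphocyte markers were at -0.78, but at -0.07 in females alone. Erythroid markers, not among the 5 lists, were at 2.48, so a changed mix of cell types was not excluded. The alternative scalings moved the median of all genes by only -0.0147 to 0.00234 and left a lowest median of 1.74 for the list. A scaling factor moves all genes of a library alike, and the median over all genes was -0.00615, against 1.75 for the list. These values argue against scaling as the source of the rise relative to other genes. A shift common to all genes was not tested and stays open. Dividing nucleated erythroid cells stay a candidate explanation: over the 6 hypoxia libraries mitosis and erythroid scores had a Pearson r of -0.517 (exact permutation p = 0.319) and a Spearman rho of -0.0857 (exact permutation p = 0.919), and r was 0.479 without the 2 libraries farthest from the median. A change in heart cells themselves, under hypoxia or by sex, stays open and was not tested.

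In 4 genes the count was 0 in a whole group and at least 20 in every other library. Whether these zeros arose in the samples or in the quantification was not decided. Zeros in a single library occurred as well: each library had 1 to 10 genes with 0 reads there and at least 20 in every other library. Zeros shared by 3 libraries were searched for only within the groups. Rpl35a-ps2, a ribosomal pseudogene whose reads are uncertain, had 0 reads in normoxic males and 37 to 383 in hypoxic males, at least 211-fold higher. The pyruvate carboxylase gene Pcx had 0 reads in normoxic females and 60 to 192 in hypoxic ones, at least 112-fold higher, and Zfp746, chosen after its values were seen, had 0 and 70 to 138, at least 108-fold higher. Hdgfl2 had 0 in hypoxic females.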
